A study of Mus musculus with 9 samples.

How the data were processed

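RNA was measured in LSK cells (lineage-negative, Sca1-positive, cKit-positive) sorted from the bone marrow of 9 mice, 3 in each of 3 groups: naive mice, mice at 3 days after immunization for experimental autoimmune encephalomyelitis (EAE) and immunized mice given the β3-adrenergic antagonist SR59230A over those 3 days. Per the labels' protocols, RNA was prepared with the RNeasy micro kit. The libraries are labelled with IonCode barcodes, and the sequencer and library kit are not given in the sources used here. Samples were put in groups by their labels, which describe them as separate mice. Replicate numbers follow the order of deposition and pair nothing.

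The authors deposited 1 table of whole numbers for 14940 gene symbols and 9 libraries, of which 14423 genes are above 0 in every library. The aligner, the counting tool, the genome build and the annotation are not given in the sources used here, so genes are named by symbol, without coordinates. The submitters' processing notes name DESeq2 without a version or a role. Against GENCODE M21, 14132 symbols matched. The deposited values are a score, made by the authors in a way that their labels do not describe, and not read counts. Over 4577 genes with a mean of at least 500, principal components 7 and 8 of ln(value + 1) held 6.7e-05% and 5.94e-05% of the variance, against 2.44% to 55.3% for components 1 to 6. The values obey 2 linear relations across the 9 libraries in every range of expression, with residuals between 0.992 and 1.25 times the rounding error and between 0.516% and 11.1% of counting noise. Independent read counts cannot do so. The missing directions lay within the groups (99.4% and 99.8%), so the spread between replicates is understated if they were taken out of values that held them. Depth cannot be recovered, and differences between genes in counting precision are unknown.

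The values were scaled by median-of-ratios factors (0.9005 to 1.107), genes with a value of at least 10 in 3 libraries were kept (13018), and log2(value + 1) was analysed, a scale that understates fold changes of low genes. Group differences were tested, 2-sided, with limma-trend (limma 3.58.1 in R 4.3.3) over all 9 libraries, with Benjamini-Hochberg adjustment and a threshold of 0.05. The model held a coefficient per group and the 2 missing directions as covariates, which leaves 4 residual degrees of freedom and a prior of 7.52. The comparisons, the gene lists, the rule for named genes and the alternatives not said below to be added later were chosen before the data were examined. The planned tests assumed read counts, with limma-trend named for any other unit. Tests for read counts were run first and set aside once the relations were found, so their calls had been seen. The 2 covariates, the scaling and the filter were chosen after that, on the grounds of the simulation below and the library sums.

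The analysis was tested on simulated values with 200 of 13018 genes changed. With 2 directions removed within groups, a model with group coefficients alone gave 33.5% false calls for EAE against naive, 31.2% for treated against EAE and 40.5% for treated against naive mice. With the directions as covariates, false calls were 2.54%, 3.68% and 3.17%. For EAE against naive, 28.4% of genes changed 1.5-fold, 52.2% of those changed 2-fold and 84.8% of those changed 4-fold were recovered. For treated against EAE these shares were 34.3%, 59.7% and 90.9%, and for treated against naive 35.8%, 56.7% and 81.8%. A list of 20 genes changed 1.5-fold had adjusted p = 2.07e-24, 1.62e-26 and 2.79e-17 in these comparisons, and 0 of 100 unchanged lists were called. The simulated genes vary independently, so this need not carry over to lists of genes that vary together. In the deposited values, splits that mix the groups called up to 19 of 28 lists. Such splits keep part of any difference between the groups, so that number does not show what lists without an effect would give. The simulated spread within groups was also alike in all directions, and only 200 genes were changed. The deposited values need not be so, and the rates of false calls and of recovery may not hold for them.

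Of 29 gene lists fixed in advance, 28 had at least 5 tested genes and were tested with limma's camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. Ranges of a list's adjusted p over alternatives are for camera at the preset correlation. With an estimated correlation camera also uses the 4 residual degrees of freedom, so a call lost there need not come from members that vary together. In EAE against naive mice the natural killer and mast cell lists had estimates of -0.0626 and -0.0307, below the preset value. Their calls were lost all the same (adjusted p = 0.301 for both). Of the listed symbols, 163 were not in the table, some of them second names of a gene. The ribosomal list had 16 of its 80 symbols in the table and the heat shock list 8 of 13. Results for these lists cover only that part of them. Members were also adjusted over the list alone. The adrenergic receptor list had too few tested genes, and Adrb1 and Adrb3 of it are given as values. Named genes were, for each comparison, the 10 largest rises and 10 largest falls among called genes without overlap between groups and with a mean of at least 10 in the higher group, leaving out predicted and olfactory receptor genes. Where few genes passed, the 5 with the smallest p in each direction were taken, and for lists up to 4 members with the smallest p, with further members where a list moved. Some genes due under these rules are not reported here. The chemosensory receptor genes, Csf2rb, Mecom and the libraries singled out for a gene were chosen after their values were seen.

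The covariance across genes of the changes by immunization and by antagonist was set beside 100 draws of normally distributed values with no group effect. The alternatives were a pseudocount of 0.1, no filter, a mean of at least 10 or (added after seeing the data) of at least 100, for the movement back towards naive a mean of at least 50, each library left out, only the 6 libraries compared and, added after seeing the data, the group model without the 2 directions, no scaling, upper-quartile scaling, the chemosensory level as a covariate and the 2 most similar treated libraries averaged. Replicate pairs differed by an SD of 0.249 to 0.52 in log2 value. The closest pair, SR59230A-treated replicates 2 and 3, had a squared difference 1.15 times counting noise over genes at 50 to 500, where depth is only assumed. The other pairs within groups had 1.92 to 5.9 times. A value near counting noise does not show that these 2 libraries come from separate mice, and they were kept as separate on the labels alone. Deviations of log2 value from the group mean were correlated across groups. The correlations ran from -0.703 (naive replicate 1 with treated replicate 2) to 0.838 (EAE replicate 1 with treated replicate 2). The tests take the libraries as independent apart from the 2 missing directions, so their SE and p may be off. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y were above 0 in all 9 libraries, and Xist was not among the deposited symbols.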

Results

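Gene expression was measured in LSK cells, the lineage-negative, Sca1-positive and cKit-positive fraction of mouse bone marrow that holds stem cells and multipotent progenitors. The 9 libraries came from 3 naive C57BL/6 mice, 3 mice taken 3 days after immunization for experimental autoimmune encephalomyelitis (EAE), and 3 immunized mice given SR59230A, a β3-adrenergic receptor antagonist, over the same 3 days. Immunization combined complete Freund's adjuvant, an oil emulsion with mycobacteria, with residues 35 to 55 of myelin oligodendrocyte glycoprotein. There is no group given adjuvant alone, so effects of adjuvant and peptide cannot be told apart. The group labels name no vehicle for the EAE mice without SR59230A, so the antagonist is not separated from its administration. The labels describe the replicates of each group as separate mice. The deposited whole numbers are adjusted values and not read counts, so the sequencing depth is unknown and no counting interval can be given. The adjusted values summed to between 8641735 and 10387955 per library over 14940 genes, of which 13018 were tested. On the first principal component, which held 45.6% of the variance, the naive libraries lay between 33.1 and 42.3 and the other 6 libraries between -24.7 and -11.5. EAE replicate 2 stood apart on the third component (13.2% of the variance), at -36.0.

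**Figure D1:**
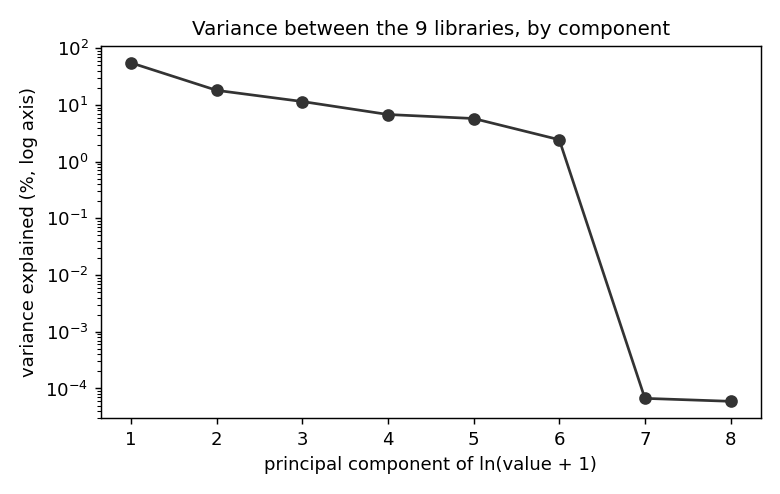
Percent of the variance between the 9 libraries (log axis) held by each principal component of the natural logarithm of value + 1, over 4577 genes with a mean value of at least 500. Components 1 to 6 hold between 2.44% and 55.3%, and components 7 and 8 hold 6.7e-05% and 5.94e-05%, so 2 directions of variation are missing from the deposited values.

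The first comparison asks what immunization did to LSK cells within 3 days. Genes of granulocyte-monocyte progenitors rose: Ms4a3, a marker of these progenitors, stood at 18.6 ± 2.99 in naive mice and 762 ± 158 in EAE mice (SD, n = 3 each), 39.5-fold higher. Elane, which encodes neutrophil elastase, was 30.5-fold higher, at 1292 ± 393 against 43.5 ± 19.8. Of 21 stem-cell genes 13 fell, among them the transcription factor gene Hlf at 1174 ± 104 against 3248 ± 212, but the list was not called with an estimated correlation (camera adjusted p = 0.0862). Among the genes of the sort gate, Kit fell by 0.43 ± 0.09 on the log2 scale (SE) and Ly6a, which encodes Sca-1, rose by 0.46 ± 0.12. The rise of Ly6a was lost without naive replicate 1 (limma-trend with Benjamini-Hochberg adjustment, adjusted p = 0.0619) and without scaling (0.0758), with 0.00752 to 0.0758 over all its alternatives.

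**Figure D2:**
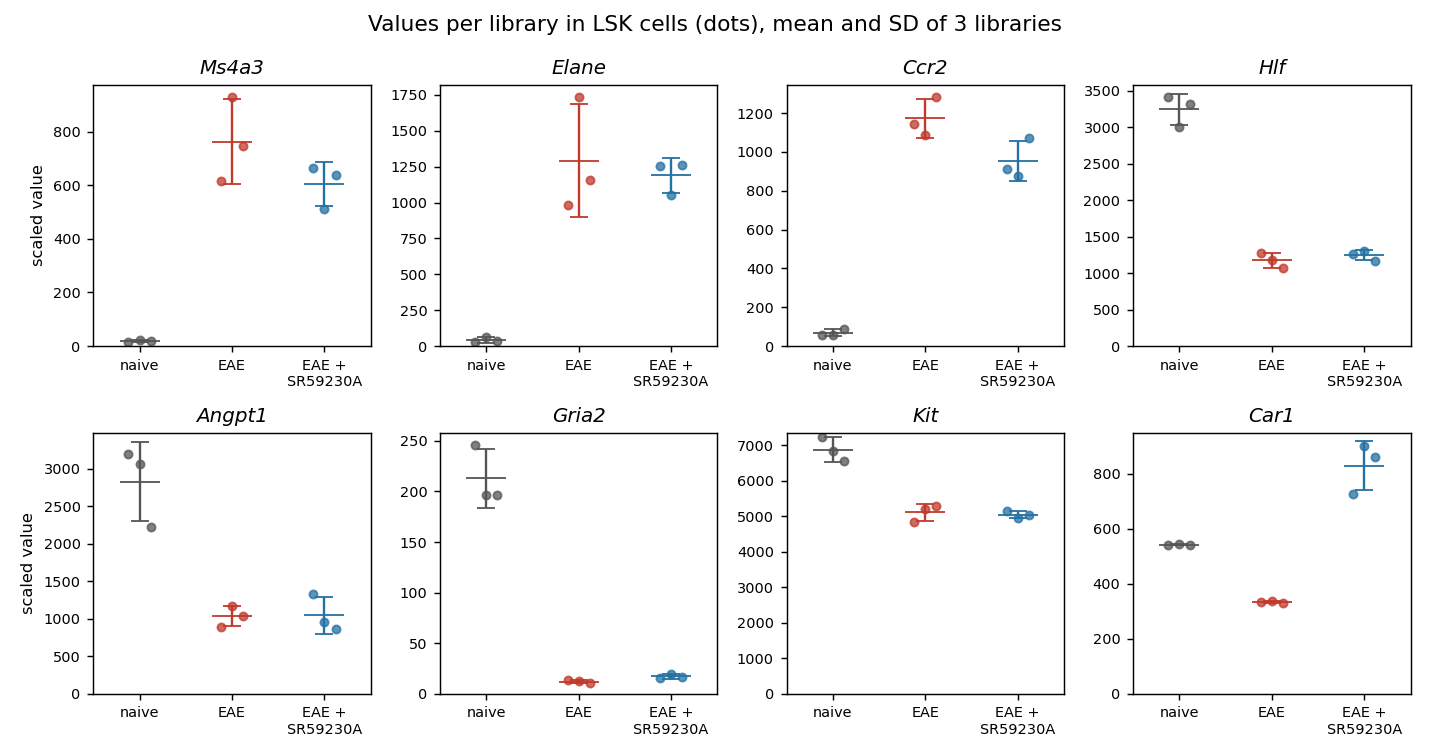
Scaled values (linear axes from 0) of 8 genes in each library of the naive, EAE and SR59230A-treated EAE groups. Dots are libraries, horizontal bars the group means and error bars the SD of 3 libraries. Ms4a3 lies between 15.2 and 20.8 in the naive libraries and between 510 and 928 in the other 6, and Car1 is higher in each treated library (728 to 900) than in each EAE library (329 to 337).

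Of the 18 tested granulocyte-monocyte progenitor genes, 14 rose and none fell, with a median log2 fold change of 1.67. Adjusted over the list alone, 16 rose. Beside Ms4a3 and Elane, the granule protease genes Ctsg and Prtn3 rose by 3.53 ± 0.18 and 2.30 ± 0.12, and Mpo, which encodes myeloperoxidase, rose by 2.11 ± 0.22. The colony-stimulating factor receptor genes Csf1r (2.29 ± 0.25) and Csf2rb (1.63 ± 0.18) rose as well. Against all other genes the list was higher by limma's camera test with a preset correlation of 0.01 (Benjamini-Hochberg adjusted p = 1.08e-16), and the call held with an estimated correlation (adjusted p = 0.0199). The list of mature neutrophil genes, a cell type outside the gate, also ranked higher by camera (adjusted p = 0.0142, but adjusted p = 0.521 with an estimated correlation). Of its 14 tested genes, 12 had a positive log2 fold change (median 1.13), 2 rose and 1 fell, and adjusted over the list alone 3 rose and 1 fell. Cxcr2, the receptor for neutrophil-attracting chemokines, rose by 2.80 ± 0.35, while Padi4, which encodes a histone-citrullinating enzyme, fell by 0.47 ± 0.10. The neutrophil granule gene S100a8 varied widely within the groups, at 2758, 729 and 3682 in the EAE libraries and 642, 482 and 1306 in the naive libraries. The camera call for mature neutrophil genes was lost without EAE replicate 1, naive replicate 2 or EAE replicate 3, with adjusted p from 0.06 to 0.213 in those fits and from 4.96e-05 to 0.213 over all alternatives with the preset correlation.

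Beyond that list, the largest rises in EAE mice included several myeloid receptor and secreted protein genes. Ccr2, the chemokine receptor of inflammatory monocytes, rose 17.5-fold, from 68.3 ± 18.1 to 1172 ± 100. The myeloid lectin receptor gene Clec5a rose 25.7-fold, the immunoglobulin-superfamily gene Igsf6 16.8-fold, the haptoglobin gene Hp 14.9-fold and the myeloid receptor gene Trem3 12.9-fold. Tmem215 rose 21.2-fold. Dmkn and Tctex1d1 were near 1 in naive mice (1.28 ± 0.532 and 0.967 ± 0.0408) and reached 117 ± 52.2 and 90.6 ± 39.2. All of these passed by limma-trend with Benjamini-Hochberg adjustment, with adjusted p no higher than 1.75e-05, and lay above every naive library in all 3 EAE libraries.

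Of the 21 tested stem-cell genes, 13 fell and none rose, with a median log2 fold change of -0.63. Adjusted over the list alone, 14 fell and 1 rose. Hlf fell by 1.48 ± 0.10, Angpt1, which encodes a ligand of the Tie2 receptor, by 1.45 ± 0.18 and the guidance receptor gene Robo4 by 1.06 ± 0.13. Mecom, a transcription factor gene required for stem-cell maintenance, fell by 0.87 ± 0.14. The list was lower by camera (adjusted p = 4.59e-09), a call lost with an estimated correlation (adjusted p = 0.0862). The estimate was 0.0334, and fry called the list lower (fry adjusted p = 0.00326). Slamf1, which encodes the stem-cell surface marker CD150, stood at 77.0 ± 1.12 and 96.3 ± 18.5 and did not pass. Cd34 did not pass either, with a log2 fold change of -0.22 ± 0.10.

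Some lymphoid genes were lower in EAE mice. Of 16 lymphoid-primed progenitor genes, 9 fell and 1 rose, and adjusted over the list alone 11 fell and 1 rose. The recombinase genes Rag1 and Rag2 fell by 1.54 ± 0.40 and 0.79 ± 0.19, the cytokine receptor gene Flt3 by 0.44 ± 0.10 and the transcription factor gene Mef2c by 0.61 ± 0.13. Camera placed the list lower (adjusted p = 0.000455, but adjusted p = 0.418 with an estimated correlation). Of 10 B cell genes, 3 fell, and adjusted over the list alone 5 fell: Fcmr, the IgM Fc receptor gene, fell by 2.60 ± 0.44, Bank1, a B cell scaffold gene, by 1.11 ± 0.24 and Igll1, part of the surrogate light chain, by 1.93 ± 0.49. The list had camera adjusted p = 0.00649 and adjusted p = 0.301 with an estimated correlation. The fall of Igll1 did not pass without naive replicate 3 (limma-trend with Benjamini-Hochberg adjustment, adjusted p = 0.0502, with 0.00983 to 0.0502 over its alternatives). The lymphoid gene Il7r did not pass, at 353 ± 47.6 in naive and 372 ± 165 in EAE mice. EAE replicate 2 had the lowest Il7r value (188) of the 9 libraries.

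Some genes of the cell cycle and of oxidative phosphorylation rose by smaller amounts. Of 24 DNA replication genes, 9 rose and none fell (16 adjusted over the list alone), among them Rrm2, a subunit gene of ribonucleotide reductase, by 0.94 ± 0.09. Of 25 G2/M genes, 13 rose and none fell (19 adjusted over the list alone), including Birc5, which encodes survivin, by 0.61 ± 0.09 and the mitotic kinase gene Plk1 by 0.62 ± 0.11. Both lists passed camera (adjusted p = 4.95e-08 and 2.71e-08), with adjusted p = 0.301 for each with an estimated correlation. Of 61 oxidative phosphorylation genes, 16 rose and none fell (32 adjusted over the list alone), with a median of 0.29 and Ndufb5, a complex I subunit gene, at 0.57 ± 0.09. That list had camera adjusted p = 6.56e-11, and adjusted p = 0.418 with an estimated correlation. Of 16 unfolded protein response genes, 7 rose and none fell (8 adjusted over the list alone), such as the endoplasmic reticulum gene Sdf2l1 by 1.26 ± 0.18. For these genes camera gave adjusted p = 0.000492 and adjusted p = 0.446 with an estimated correlation.

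Inflammatory and other lineage lists moved with fewer members. Of 21 NF-kB and inflammatory response genes, 5 rose and none fell (6 adjusted over the list alone), including Bcl3, an NF-kB cofactor gene, by 1.43 ± 0.16 and the adaptor gene Myd88 by 0.79 ± 0.11. By camera the list had adjusted p = 0.00882, and adjusted p = 0.301 with an estimated correlation. Of 28 interferon-stimulated genes, 5 rose and none fell (6 adjusted over the list alone), among them Bst2, which encodes tetherin, by 0.51 ± 0.09. Here camera gave adjusted p = 0.0131, and adjusted p = 0.494 with an estimated correlation. Of 8 mast cell and basophil genes, 3 rose and none fell, over all genes and adjusted over the list alone, with the basophil protease gene Mcpt8 up by 2.58 ± 0.28 and the histamine synthesis gene Hdc by 1.95 ± 0.26. Their camera adjusted p was 0.0131, with adjusted p = 0.301 with an estimated correlation. Of 15 erythroid genes, 4 fell and 2 rose (5 and 2 adjusted over the list alone). The carbonic anhydrase genes Car2 and Car1 fell by 1.42 ± 0.09 and 0.71 ± 0.10, while Tfrc, which encodes the transferrin receptor, rose by 0.57 ± 0.09. Camera placed the erythroid list lower (adjusted p = 0.0196, but adjusted p = 0.446 with an estimated correlation). Without naive replicate 3 the NF-kB call was lost (camera adjusted p = 0.0623, with 0.00143 to 0.694 over its alternatives). Without EAE replicate 3 the interferon call (camera adjusted p = 0.188, with 0.000588 to 0.971) and the erythroid call (0.0731, with 0.00557 to 0.358) were lost.

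Among the largest falls in EAE mice was that of Gria2, a glutamate receptor subunit gene, from 213 ± 28.9 to 12.1 ± 1.57, 16.6-fold. Also lower were Sele, which encodes E-selectin (log2 fold change -3.71 ± 0.87), the troponin gene Tnni1 (-3.06 ± 0.68), the signalling regulator gene Rgs4 (-3.02 ± 0.85), Fam171b (-2.84 ± 0.73) and F8, which encodes coagulation factor VIII (-2.80 ± 0.57). Cdh5, which encodes the endothelial VE-cadherin, had a log2 fold change of -2.89 ± 0.80, the eosinophil ribonuclease gene Ear6 one of -2.69 ± 0.61 and the neurotrophic receptor gene Gfra2 one of -2.46 ± 0.50. Of 9 stromal and endothelial genes, 2 fell and 1 rose (3 and 1 adjusted over the list alone), and camera did not call the list (adjusted p = 0.0552, with 0.0307 to 0.863 over its alternatives, called lower without a filter, without scaling and without EAE replicate 1). Fry called the list lower (fry adjusted p = 0.0271). Cdh5 was 123 in naive replicate 3 and between 2.08 and 35.5 in the other libraries. Its call was lost without naive replicate 1, naive replicate 3, EAE replicate 2 or EAE replicate 3 (limma-trend with Benjamini-Hochberg adjustment, adjusted p from 0.0605 to 0.0927, and from 0.00696 over all alternatives). With a pseudocount of 0.1 Sele (0.054), Rgs4 (0.117) and Fam171b (0.0535) did not pass, and Rgs4 was also lost without EAE replicate 2 (adjusted p = 0.0763 by the same test).

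In all, 1853 genes differed between EAE and naive mice by limma-trend with Benjamini-Hochberg adjusted p under 0.05. Of these, 1189 rose and 664 fell, 213 and 170 of them by at least 2-fold. A mean under 100 was found in 127 of those that rose and 175 of those that fell. Genes with a mean under 20 had a median log2 fold change of -0.35. Over all 13018 tested genes, 39.4% showed no overlap between the groups, against 10% by chance if libraries were exchangeable. The missing directions lay within the groups, which can raise such a share with no effect at all. How much of the excess over 10% comes from this is unknown, here and in the other comparisons. Without scaling 1059 genes were called (606 higher and 453 lower, 57.2% against 64.2% higher), and upper-quartile scaling turned the split to 807 higher and 910 lower (47%). The missing directions were terms of the model: without them 3485 genes were called (2062 higher and 1423 lower). Chemosensory receptor genes, a family with no known role in blood progenitors, held 0.168%, 0.148% and 0.179% of the values in the naive libraries, 0.114%, 0.119% and 0.105% in the EAE libraries and 0.0784%, 0.0859% and 0.0981% in the treated libraries. These shares did not overlap between the groups, so a term for their level also takes out differences between the groups, and calls that end with it are not shown to be technical. With that term 173 genes were called, and 10 gene lists in place of 17: 8 of the 17 were kept, 9 ended, and quiescence (camera adjusted p = 0.000752) and cAMP-responsive genes (1.43e-06) were newly called, both lower. It ended the interferon, erythroid, mast cell and unfolded protein response calls (camera adjusted p = 0.971, 0.358, 0.164 and 0.413) and the natural killer, glucocorticoid, cholesterol and ribosomal calls (0.439, 0.694, 0.704 and 0.668), and turned the NF-kB list lower (0.694). The lowest adjusted p of these 9 lists over their alternatives were 0.000588, 0.00557, 0.00201, 2.24e-06, 0.0169, 0.0155, 0.00229, 0.00143 and 0.00143.

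The next comparison asks what the β3 antagonist changed in immunized mice. A single gene passed: Car1, which encodes the carbonic anhydrase of early erythroid progenitors, stood at 333 ± 3.67 in EAE mice and 830 ± 90.1 in treated mice (SD, n = 3 each), 2.49-fold higher. Its log2 fold change was 1.32 ± 0.10 (SE), with adjusted p = 0.000516 by limma-trend with Benjamini-Hochberg adjustment, and it was higher in 3 of 3 treated libraries than in every EAE library. In naive mice Car1 was 543 ± 2.87, so that it was lower in EAE mice and higher in treated mice than in naive mice. The single values were very close, at 332, 337 and 329 in the EAE and 540, 546 and 542 in the naive libraries. Directions within the groups are missing from these values, so the SD, the SE and the p of Car1 may understate the spread between mice. At an unadjusted p under 0.05 there were 504 genes, against 650.9 given by chance. That number was 285 without SR59230A-treated replicate 2, 788, 819 and 1093 without EAE replicates 1, 2 and 3 in turn, 945 without naive replicate 2, 1348 without the missing directions as terms and 1120 with the 6 libraries alone, so it lies on either side of chance. Of all genes, 16.2% separated the groups, against 10% for exchangeable libraries. The directions missing within the groups can raise this share by themselves, so it does not show an effect of the antagonist. The median SE of a log2 fold change was 0.15 and the median unadjusted 95% interval reached 0.32 to either side. In simulated values, 34.3% of genes changed 1.5-fold were recovered in this comparison.

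Erythroid genes and interferon-gamma-inducible genes ranked higher in treated mice by camera with the preset correlation, though not with an estimated correlation (adjusted p = 0.168 for both), and fry called 0 lists in this comparison. All 15 tested erythroid genes had a positive log2 fold change (median 0.64), of which 1 passed over all genes and 3 adjusted over the list alone. Beside Car1, the water channel gene Aqp1 had a log2 fold change of 1.45 ± 0.24 without passing (128 ± 13 against 48.1 ± 14.3). Of the 23 interferon-gamma-inducible and antigen presentation genes, 22 had a positive log2 fold change (median 0.22). None of them passed over all genes, and 4 did adjusted over the list alone. These were the immunity-related GTPase gene Igtp (904 ± 52.5 against 570 ± 58.9), the guanylate-binding protein genes Gbp2 (560 ± 74.5 against 333 ± 80.1) and Gbp4 (239 ± 14.6 against 136 ± 54.8) and Ciita, the activator of MHC class II genes (81.6 ± 2.88 against 45.4 ± 2.21). Each of the 2 lists had camera adjusted p = 6.93e-12 with the preset correlation. Of the 10 splits of these 6 libraries, 8 called at least as many lists as the 9 of the real one, which is among them (highest other 15).

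Lymphoid and antigen-presenting cell lists ranked higher too, with 0 members past the threshold by limma-trend over all genes or adjusted over the list alone. All 16 lymphoid-primed progenitor genes had a positive log2 fold change (median 0.20), such as Dntt, which encodes terminal deoxynucleotidyl transferase, at 0.38 ± 0.15 and Il7r at 0.81 ± 0.29. As a list they had camera adjusted p = 8.88e-07, and adjusted p = 0.311 with an estimated correlation. All 10 B cell genes were positive (median 0.44, adjusted p = 0.000469 by camera, but adjusted p = 0.244 with an estimated correlation). Of 14 monocyte, macrophage and dendritic cell genes, 13 were positive, including the MHC class II genes H2-Eb1 (200 ± 42.9 against 118 ± 24.1) and H2-Aa (209 ± 2.65 against 125 ± 37.7). That list had adjusted p = 5.7e-05 by camera and adjusted p = 0.168 with an estimated correlation. The 28 interferon-stimulated genes had a median of 0.13 (adjusted p = 5.83e-05 by camera, but adjusted p = 0.347 with an estimated correlation). Their call was lost without EAE replicate 2 (camera adjusted p = 0.115, with 1.63e-09 to 0.948 over its alternatives). The chemosensory level as a term, which follows the groups, kept 3 of the 9 list calls and newly called 6 lists. It ended the interferon, monocyte and B cell calls (camera adjusted p = 0.948, 0.769 and 0.515, with lowest values over their alternatives of 1.63e-09, 1.94e-08 and 1.61e-06). The natural killer, glucocorticoid and heat shock calls ended with it too (camera adjusted p = 0.547, 0.769 and 0.547), the last list turning lower.

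Lists of natural killer cell genes (median 0.66) and glucocorticoid-responsive genes (median 0.18) passed camera with adjusted p = 0.017 each, and heat shock genes (median 0.18) with adjusted p = 0.0333. With an estimated correlation these 3 lists had adjusted p = 0.25, adjusted p = 0.311 and adjusted p = 0.555, and none of their members passed over all genes or adjusted over the list alone. Each call was lost without SR59230A-treated replicate 1, with camera adjusted p = 0.242, 0.0551 and 0.327. The natural killer call was also lost without SR59230A-treated replicate 2 or EAE replicate 2, the glucocorticoid call without EAE replicate 1 or 3 and the heat shock call without EAE replicate 2 or 3. Over all alternatives the 3 lists had adjusted p from 0.00063 to 0.547, from 0.00328 to 0.769 and from 0.00335 to 0.547. Stem-cell genes (median 0.02, adjusted p = 0.571) and granulocyte-monocyte progenitor genes (median -0.10, 14 of 18 negative, adjusted p = 0.0555) were not called by camera, but the latter were called lower without SR59230A-treated replicate 3 (camera adjusted p = 0.0374), without EAE replicate 3 (0.0344), without scaling (0.0413) and with upper-quartile scaling (0.0488), with 0.0344 to 0.953 over all alternatives. G2/M genes (17 of 25 negative, camera adjusted p = 0.0601) were called lower without naive replicate 2 (0.0469), without SR59230A-treated replicate 2 (0.0283) or 3 (0.0374), without EAE replicate 2 (0.00446), without scaling (0.0149), with upper-quartile scaling (0.0322) and with 2 treated libraries averaged (0.033), with 0.00446 to 0.953 over all alternatives. The oxidative phosphorylation, mature neutrophil, mast cell, stromal, T cell, unfolded protein response and cholesterol lists were not called either, but each was called under some alternative, with lowest camera adjusted p of 0.00143, 0.00393, 0.00847, 0.00847, 0.0398, 0.0256 and 0.0181 and highest of 0.368, 0.985, 0.829, 0.281, 0.948, 0.758 and 0.862. The neutrophil granule gene S100a8 differed between single libraries, at 1626, 3238 and 3737 in the treated libraries, against 2758, 729 and 3682 in the EAE libraries.

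Genes with the smallest p that did not pass included Epx, which encodes eosinophil peroxidase, at 21.8 ± 8.6 in treated and 1.98 ± 0.151 in EAE mice, and Ear6, at 44.5 ± 15.6 and 4.44 ± 3.56 (adjusted p = 0.451 for both by limma-trend with Benjamini-Hochberg adjustment). Sdc4, which encodes syndecan-4, was 168 ± 11.9 in treated and 100 ± 9.57 in EAE mice. On the lower side stood AY761185 (204 ± 9.77 against 371 ± 44.9), 5730435O14Rik (51.1 ± 2.94 against 122 ± 11.2), Gm20594 (231 ± 9.51 against 358 ± 58), Ubtfl1 (18.8 ± 2.38 against 47.1 ± 10.1) and Dennd4a (254 ± 4.56 against 339 ± 8.81). The genes of the gate did not pass, with Kit at 5049 ± 105 against 5116 ± 236 and Ly6a at 2433 ± 100 against 2099 ± 255. The adrenergic receptor gene Adrb1 was 5.31 ± 2.37 in treated, 11.5 ± 1.56 in EAE and 16.5 ± 5.24 in naive mice, none of the differences passing. Its fall from naive to treated mice passed under some alternatives (limma-trend with Benjamini-Hochberg adjustment, adjusted p from 0.0126 to 0.131). Adrb3, the receptor that SR59230A blocks, was too low to test, at 4.17 ± 0.886, 1.6 ± 1.42 and 5.75 ± 1.73. Foxp3, the regulatory T cell transcription factor gene, was also too low, at 0.339 ± 0.587, 2.65 ± 2.17 and 2.57 ± 1.06.

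**Figure D3:**
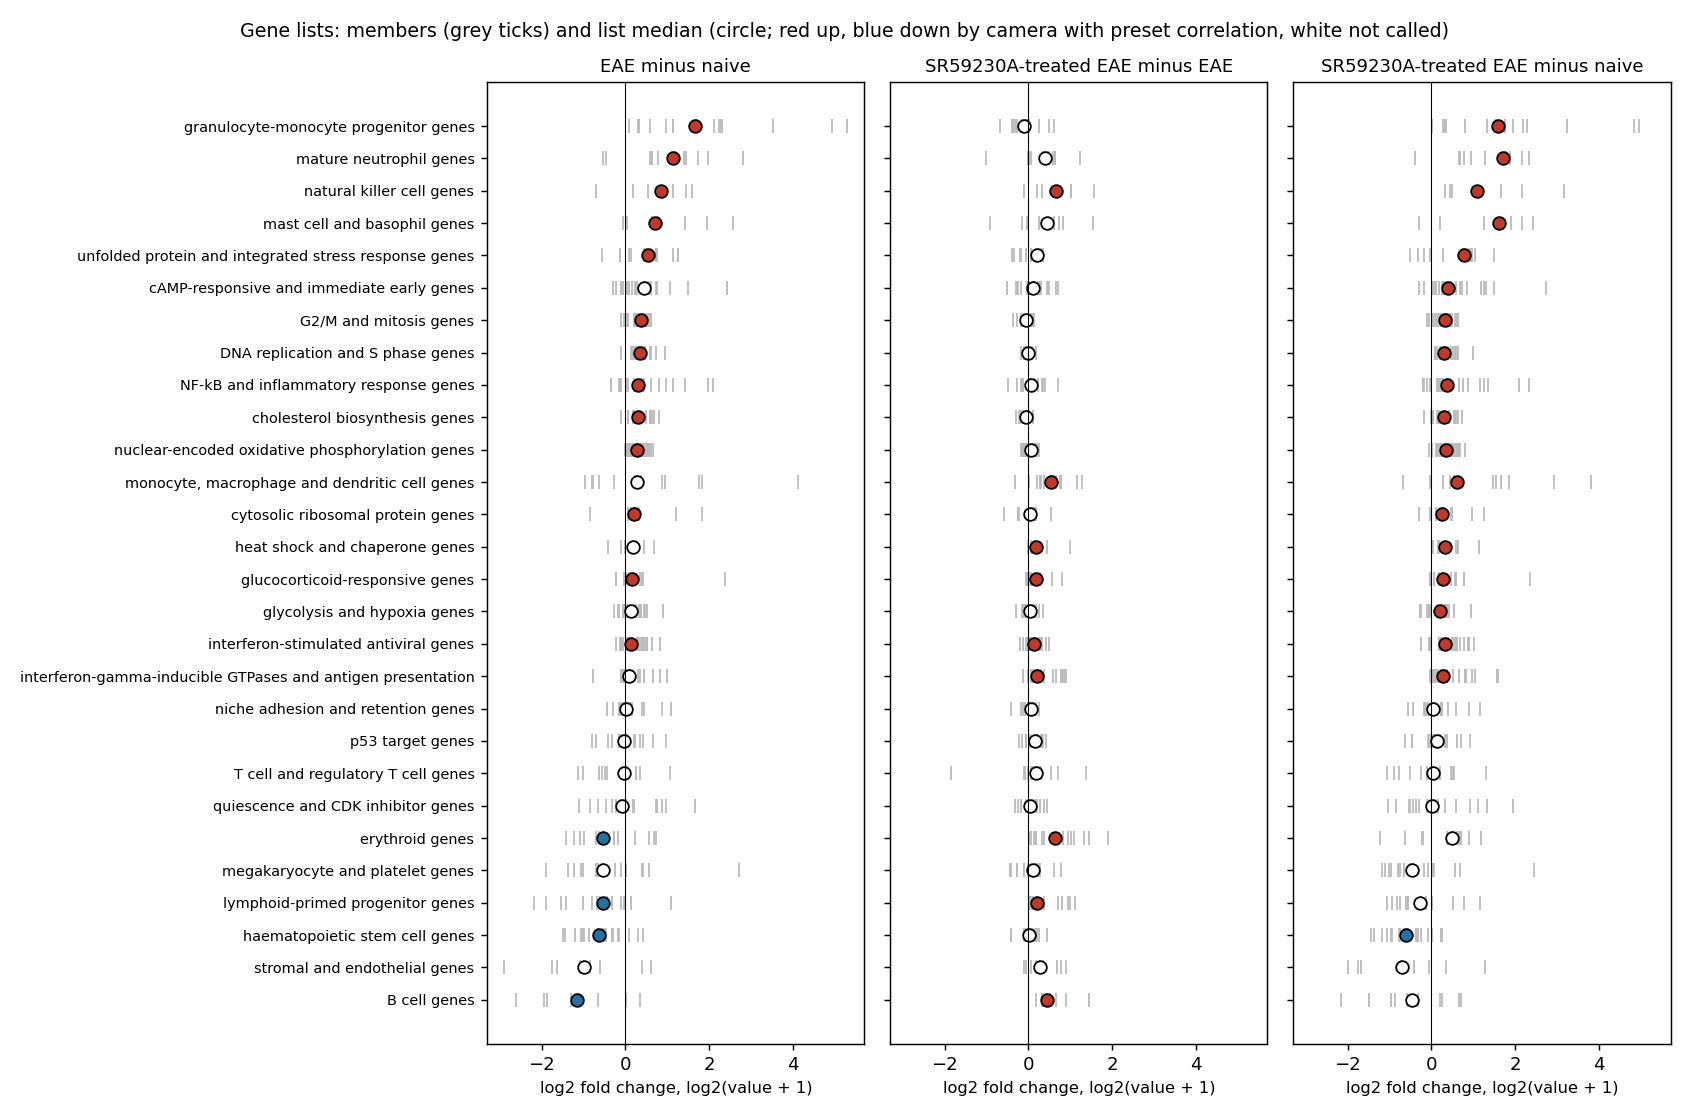
Log2 fold changes on the log2(value + 1) scale of the members (grey ticks) and the median (circles) of 28 gene lists in the 3 comparisons. Red circles are lists called higher and blue circles lists called lower by camera with a preset correlation of 0.01, white circles were not called, and with an estimated correlation 1, 0 and 1 lists were called. Granulocyte-monocyte progenitor genes have medians of 1.67, -0.10 and 1.59, and erythroid genes of -0.52, 0.64 and 0.49.

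The third comparison sets treated immunized mice against naive mice, and so holds immunization and antagonist together. The myeloid rise was present here too: Ms4a3 stood at 603 ± 82.3 against 18.6 ± 2.99 (31.2-fold), Elane at 1189 ± 120 against 43.5 ± 19.8 (28.6-fold) and Ccr2 at 953 ± 104 against 68.3 ± 18.1 (14.1-fold). Of the 18 granulocyte-monocyte progenitor genes, 13 rose and none fell (15 adjusted over the list alone), with a median of 1.59. Camera gave adjusted p = 1.29e-14, held with an estimated correlation (adjusted p = 0.0258). Of the 21 stem-cell genes, 12 fell and none rose (13 adjusted over the list alone), with a median of -0.60. Hlf fell by 1.38 ± 0.10 and Angpt1 by 1.44 ± 0.18. Stem-cell genes had camera adjusted p = 6.46e-09, and adjusted p = 0.0889 with an estimated correlation. These 2 progenitor lists were the only ones whose estimated-correlation p lay under 0.1 in any comparison, and the granulocyte-monocyte list the only one that held in that form of camera. Fry called 11 lists in EAE against naive and 14 in treated against naive mice, and ended 9 and 6 of the preset calls. Among those it called were stem-cell genes (fry adjusted p = 0.00326 and 0.00287) and DNA replication and G2/M genes (0.00918 and 0.00954 for each).

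Other large rises in treated mice were in F13a1, which encodes the A chain of coagulation factor XIII (1826 ± 290 against 145 ± 7.76), Ccl2, which encodes a monocyte-attracting chemokine (35.3 ± 17.2 against 1.91 ± 1.63), Clec5a (17.7-fold), Tmem215 (15.8-fold), Igsf6 (14.3-fold), Dmkn (45.9-fold) and Tctex1d1 (24.6-fold). The largest falls were in Gria2 (11.9-fold), Sele (11.5-fold), Rgs4, Igf2bp2, which encodes an RNA-binding protein, Gpihbp1, the taste receptor gene Tas2r136, the adhesion gene Chl1, the natriuretic peptide receptor gene Npr1, Gcsam and Ndnf, the last 8 between -2.93 and -2.21 on the log2 scale. Several of these falls rest on single libraries or on the pseudocount. Rgs4 did not pass without SR59230A-treated replicate 1 (limma-trend with Benjamini-Hochberg adjustment, adjusted p = 0.0741, with 0.0152 to 0.121 over its alternatives) nor Gpihbp1 without SR59230A-treated replicate 1 or 2 (0.0551 to 0.0642, from 0.00828 over all alternatives). Npr1 did not pass without naive replicate 1 or 3 or any 1 of the 3 treated libraries (0.0512 to 0.105, from 0.0214 over all alternatives), and Sele did not pass with a pseudocount of 0.1 (0.0643). Tas2r136 is one of the chemosensory receptor genes, which had a median log2 fold change of -0.75 in this comparison. Genes with a mean under 20 had a median of -0.54. A mean under 100 was found in 190 of the 600 genes that fell and 140 of the 1332 that rose. Ly6a rose by 0.68 ± 0.12 and Kit fell by 0.45 ± 0.09, while Flt3 (-0.27 ± 0.10) did not pass. Under some alternatives Flt3 did pass (limma-trend with Benjamini-Hochberg adjustment, adjusted p from 0.0223 to 0.133).

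Immune and stress lists held more called genes. Of 28 interferon-stimulated genes, 9 rose and none fell (14 adjusted over the list alone), such as Bst2 by 0.77 ± 0.09 and the interferon regulatory factor gene Irf7 by 0.57 ± 0.11, and of 23 interferon-gamma-inducible genes, 8 rose and none fell (12 adjusted over the list alone), such as Igtp by 0.97 ± 0.11 and Gbp3 by 0.82 ± 0.10. Camera gave adjusted p = 2.25e-05 and 6.31e-06, and adjusted p = 0.356 and adjusted p = 0.129 with an estimated correlation. Of 14 monocyte, macrophage and dendritic cell genes, 6 rose (9 adjusted over the list alone), with the monocyte gene Ms4a6c up by 1.86 ± 0.13 (camera adjusted p = 0.000162, and adjusted p = 0.129 with an estimated correlation). Of 6 natural killer genes, 4 rose over all genes and adjusted over the list alone, such as Klrb1c, which encodes NK1.1, by 1.67 ± 0.21 (camera adjusted p = 0.00148, and adjusted p = 0.129 with an estimated correlation). Of 8 mast cell and basophil genes, 4 rose (5 adjusted over the list alone), such as Mcpt8 by 2.43 ± 0.28 (camera adjusted p = 0.000841, and adjusted p = 0.129 with an estimated correlation). Of 21 NF-kB genes, 6 rose (10 adjusted over the list alone), such as Bcl3 by 1.25 ± 0.16 (camera adjusted p = 0.00166, and adjusted p = 0.238 with an estimated correlation). Of 14 mature neutrophil genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone), such as Lcn2, which encodes lipocalin-2, by 2.34 ± 0.45. Camera gave that list adjusted p = 0.00135 and adjusted p = 0.489 with an estimated correlation, and the call was lost without naive replicate 2 (camera adjusted p = 0.0564, with 1.41e-06 to 0.0564 over its alternatives). Of 16 unfolded protein response genes, 9 rose (10 adjusted over the list alone), such as the endoplasmic reticulum genes Manf by 0.96 ± 0.12 and Hsp90b1 by 1.03 ± 0.14 (camera adjusted p = 0.000149, and adjusted p = 0.41 with an estimated correlation).

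Some cell-cycle and respiratory genes rose here as well. There were 7 risers among 24 DNA replication genes (15 adjusted over the list alone), 12 among 25 G2/M genes (16 adjusted over the list alone) and 24 among 61 oxidative phosphorylation genes (41 adjusted over the list alone), with none falling. Rrm2 rose by 0.99 ± 0.09, Birc5 by 0.57 ± 0.09 and Cox5a, a cytochrome c oxidase subunit gene, by 0.66 ± 0.10. Camera gave adjusted p = 1.06e-06, 5.92e-06 and 1.09e-12, with adjusted p = 0.238, adjusted p = 0.238 and adjusted p = 0.391 with an estimated correlation. Lymphoid-primed genes (2 rose, 2 fell, camera adjusted p = 0.142), B cell genes (1 fell, adjusted p = 0.196) and erythroid genes (3 rose, 1 fell, adjusted p = 0.196) were not called as lists, and adjusted over the list alone these counts were the same. Car1 rose by 0.61 ± 0.10 and Tfrc by 0.70 ± 0.09, and Car2 fell by 1.23 ± 0.09.

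In this comparison 1932 genes were called by limma-trend with Benjamini-Hochberg adjusted p under 0.05, 1332 higher and 600 lower. Of all tested genes, 48.8% showed no overlap between the groups (10% for exchangeable libraries, a share that the directions missing within the groups can raise). Without scaling, which shifted the median of all log2 fold changes by -0.12, 1073 genes were called (489 higher and 584 lower, 45.6% against 68.9% higher), and with upper-quartile scaling 835 were higher and 954 lower (46.7%). The count was 1234 without naive replicate 1, 2967 without EAE replicate 2, 3327 without EAE replicate 3, 3920 without the missing directions as terms (2303 higher and 1617 lower), 4442 with the 6 libraries alone and 23 with the chemosensory level, which follows the groups, as a term. With that term 7 lists were called in place of 19, of which 5 were kept, 1 turned lower (cAMP-responsive genes, camera adjusted p = 5.48e-10) and 1 was new (quiescence genes, lower, 9.83e-05). The interferon, interferon-gamma, monocyte, natural killer, mast cell, unfolded protein and DNA replication calls ended (camera adjusted p = 0.922, 0.249, 0.895, 0.373, 0.267, 0.751 and 0.229) while the NF-kB list turned lower (0.267). The glucocorticoid, glycolysis, ribosomal, heat shock and cholesterol calls ended too (0.58, 0.196, 0.895, 0.341 and 0.74). Over their alternatives the lowest adjusted p of the first 8 of these lists lay between 1.13e-07 and 9.23e-05.

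The comparisons with naive mice, which use the same 3 naive libraries, shared 960 genes that rose and 398 that fell. Car1 was the only gene called in opposite directions, lower in EAE mice and higher in treated mice. Among the 3 groups 1728 genes differed by limma-trend with Benjamini-Hochberg adjusted p under 0.05, 1016 without naive replicate 1, 2894 without EAE replicate 3, 962 without scaling, 3726 without the missing directions as terms and 139 with the chemosensory level as a term.

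Whether the antagonist moved genes back towards naive levels was asked across all 13018 genes. The log2 fold changes from naive to EAE and from EAE to treated mice had a covariance of -0.0303 across genes, which are not independent replicates. Because both use the EAE libraries with opposite sign, the covariance lies below 0 with no effect at all: 100 simulated draws without group effects gave a mean covariance of -0.0438. A covariance as low as that observed occurred in every draw, so no movement back towards naive was detected across genes. The draws ran from -0.0491 to -0.0406, so the observed value lay outside them on the other side. Draws that overstate the noise shared through the EAE libraries could hide a movement back, so this comparison does not exclude one. The difference from the simulated covariance was 0.0135. Among the 9676 genes with a mean value of at least 50 it was 0.000408, and the share of draws with a covariance as low as observed was 0.634. It changed sign without EAE replicate 1 (-0.00478) and without the missing directions as terms (-0.000262), with no share of draws under 0.05 in either case (0.0594 and 0.446). Without a single library it ranged from -0.00478 to 0.021, with 0.00119 without SR59230A-treated replicate 1, 0.00176 without EAE replicate 3, 0.00321 without SR59230A-treated replicate 3, 0.00487 without naive replicate 2, 0.00676 without naive replicate 3 and 0.021 without SR59230A-treated replicate 2.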

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

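The tests without the 2 directions, without scaling, with upper-quartile scaling, with a mean of at least 100, with the chemosensory level and with 2 treated libraries averaged were chosen after seeing the data, and the others were planned. No paired analysis was possible because the labels describe separate mice and give no pairing between the groups. The planned scaling and tests for read counts were run first, before the 2 relations were found, and set aside without values here, since the values are not read counts. Without the 2 directions 3485 (EAE against naive), 3920 (treated against naive) and 3726 (any of 3 groups) genes were called, and in the simulation that fit gave many false calls. The simulated rates need not hold for the deposited values, so the added calls are not shown to be false. For the next values the cause was not tested. Without scaling the counts were 1059, 1073 and 962, and with the chemosensory level, which does not overlap between the groups and so also takes out group differences, 173, 23 and 139. With only 6 libraries treated against naive gave 4442. Leaving out a library gave 1234 to 3327 genes for treated against naive and 1016 to 2894 for the 3 groups. The single gene called for treated against EAE, Car1, was called under every alternative run, all of which use the same adjusted values. List calls for EAE against naive, treated against EAE and treated against naive numbered 17, 9 and 19, and 1, 0 and 1 with an estimated correlation. With fry they were 11, 0 and 14, of which 8, 0 and 13 were among the preset calls and 3, 0 and 1 were new. With the chemosensory level they were 10 in the first and 7 in the last, and without scaling 16 for treated against EAE. The chemosensory level turned lists round: NF-kB genes (camera adjusted p = 0.694, 0.0162 and 0.267 in the 3 comparisons), cAMP-responsive genes (1.43e-06, 2.25e-11 and 5.48e-10), quiescence genes for treated against EAE (0.000512), heat shock genes for treated against EAE (0.547) and naive (0.341) and cholesterol genes for treated against naive (0.74). Without EAE replicate 2 cholesterol genes turned for treated against EAE (0.0261, with 0.0181 to 0.862 over the libraries left out). The movement back towards naive had a difference in covariance of -0.00478 to 0.021 over the libraries left out and of -0.000262 without the 2 directions. Of the other tests of named genes 4703 kept their side of the threshold, 113 lost it and 121 gained it, with 0 reversed. The chemosensory level was not among them, and with it 19 (EAE against naive) and 145 (treated against naive) of the called genes changed sign. For lists these numbers were 1293, 155 and 53. Depth is unknown, so its limit cannot be given.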

Other observations

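All tests of explanations in this part were chosen only after the results were seen, while the gene lists were fixed in advance.

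Platelet and adhesion genes moved in opposite directions within their lists in EAE mice. Of 16 megakaryocyte and platelet genes, 2 rose and 3 fell (3 and 5 adjusted over the list alone), with Selp, which encodes P-selectin, up by 2.71 ± 0.11 (SE, n = 3 mice per group) and Mmrn1, which encodes multimerin-1, at a log2 fold change of -1.36 ± 0.13, and camera did not call the list (adjusted p = 0.0672, but 0.0485 without EAE replicate 1 and 0.0459 without EAE replicate 2, with 0.0459 to 0.223 over all alternatives). Of 19 niche adhesion genes, 4 rose and 2 fell over all genes and adjusted over the list alone, such as the prostaglandin receptor gene Ptger4 by 0.88 ± 0.16 (camera adjusted p = 0.316, but called higher by fry with adjusted p = 0.00988). Of 18 quiescence genes, 2 rose and 4 fell (4 and 4 adjusted over the list alone), with the transcription factor gene Klf2 up by 1.67 ± 0.24 and Txnip, a thioredoxin-binding protein gene, at -1.10 ± 0.18 (camera adjusted p = 0.446). Of 20 glycolysis and hypoxia genes, 3 rose (5 adjusted over the list alone), such as Ldha, which encodes lactate dehydrogenase A, by 0.90 ± 0.13 (camera adjusted p = 0.0513, but 0.0179 without EAE replicate 3, 0.0307 without a filter and 0.0492 with upper-quartile scaling, with 0.0179 to 0.128 over all alternatives). Of 14 T cell and regulatory T cell genes, 2 fell over all genes and adjusted over the list alone, with Lck, a T cell kinase gene, at -0.55 ± 0.11 (camera adjusted p = 0.163). The list of monocyte, macrophage and dendritic cell genes had 2 risers, Ccr2 and Ms4a6c (camera adjusted p = 0.0805, but 0.049 without EAE replicate 2, 0.0377 without scaling and 0.0381 with upper-quartile scaling, with 0.0377 to 0.858 over all alternatives, and called higher by fry with adjusted p = 0.00918), and interferon-gamma-inducible genes 2 risers and 1 that fell (camera adjusted p = 0.163). Adjusted over the list alone, 4 rose and 1 fell in each of these lists.

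The remaining lists in EAE mice moved with few members. Of 13 glucocorticoid-responsive genes, 3 rose, among them the metallothionein gene Mt1 by 2.38 ± 0.18 (camera adjusted p = 0.0469, and adjusted p = 0.418 with an estimated correlation). Of 17 cholesterol genes, 3 rose (camera adjusted p = 0.0143, and adjusted p = 0.524 with an estimated correlation), of 16 ribosomal protein genes, 1 rose (0.0343, and adjusted p = 0.521 with an estimated correlation) and of 6 natural killer genes, 2 rose (0.0374, and adjusted p = 0.301 with an estimated correlation). Adjusted over the list alone these counts were the same. The glucocorticoid call was lost without any 1 of 7 libraries (camera adjusted p from 0.0509 to 0.178: naive replicates 1 and 3, EAE replicates 2 and 3 and the 3 treated libraries), the ribosomal call without EAE replicate 1 or 2 or naive replicate 1 or 3 (0.0635 to 0.0915), the cholesterol call without naive replicate 3 or EAE replicate 2 (0.141 to 0.347) and the natural killer call without naive replicate 2, EAE replicate 3 or any treated library (0.0595 to 0.0976). The cAMP-responsive (adjusted p = 0.12), p53 (0.854) and heat shock (0.248) lists were not called by camera. The cAMP-responsive list was called higher without EAE replicate 1 (0.0102), without naive replicate 2 (0.00179), without scaling (0.0346) and with upper-quartile scaling (0.0472), with 1.43e-06 to 0.747 over all alternatives. The chemosensory level as a term ended the natural killer, glucocorticoid, cholesterol and ribosomal calls (0.439, 0.694, 0.704 and 0.668). In treated against naive mice camera called glucocorticoid (adjusted p = 0.0019, and adjusted p = 0.238 with an estimated correlation), ribosomal (0.0206, and adjusted p = 0.497 with an estimated correlation), glycolysis (0.0247, and adjusted p = 0.454 with an estimated correlation), cAMP-responsive (0.0482, and adjusted p = 0.64 with an estimated correlation), heat shock (0.0482, and adjusted p = 0.489 with an estimated correlation) and cholesterol genes (0.0482, and adjusted p = 0.612 with an estimated correlation). Those 6 lists held 4, 1, 5, 2, 2 and 2 risers over all genes and 4, 1, 5, 2, 2 and 3 adjusted over the list alone. The last 3 calls were lost without 6, 7 and 4 of the libraries in turn (0.0584 to 0.853, 0.0533 to 0.205 and 0.0573 to 0.313), EAE replicates 1 and 3, naive replicate 3 and SR59230A-treated replicate 1 for each of them, naive replicate 1 and EAE replicate 2 for the first pair and SR59230A-treated replicate 2 for heat shock genes, the ribosomal call without naive replicate 1 or 3 (0.0553 to 0.0629) and the glycolysis call without SR59230A-treated replicate 1 (0.0502). The median, mean and test differed in sign for quiescence genes in EAE mice (median -0.07, mean 0.07, ranked lower) and treated mice (median 0.02, mean 0.13, ranked lower against naive), for T cell genes in treated against naive mice (median 0.03, mean -0.03, ranked lower) and for p53 genes in EAE mice (median -0.02, mean 0.01, ranked higher).

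Granulocyte-monocyte progenitor genes ranked higher and stem-cell genes lower in EAE than in naive mice by camera with the preset correlation, and with an estimated correlation the stem-cell call was lost (adjusted p = 0.0862). Carry-over of mature neutrophils, which the lineage gate should remove, is argued against as the whole cause: 14.3% of the mature neutrophil genes lay above every naive library in every EAE library, against 83.3% of the progenitor genes. As carry-over would give, 12 of the 14 neutrophil genes had a positive log2 fold change (median 1.13, with wide spread within groups), so a part in some libraries stays open. A dilution of stem cells by other cells cannot be told apart from a change within them: the 21 stem-cell genes did not fall by a common factor (heterogeneity statistic 246, limit 31.4 at 20 degrees of freedom), but diluting cells that express some of these genes would give unequal falls too. A change of the sorted population with the gate, since Ly6a rose, and an effect of immunization on the cells may both contribute and were not tested against each other.

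Erythroid, interferon-gamma and lymphoid lists ranked higher in treated than in EAE mice by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.168, adjusted p = 0.168 and adjusted p = 0.311), and fry called 0 lists in this comparison. A single deviating library, EAE replicate 2, is argued against as the whole cause, since without it the list medians kept 80.1%, 102% and 79.7% of their size. Red cell precursors in the sort cannot be told apart from a change within LSK cells: the 5 late erythroid genes had a median of 0.96 (0.957 to 3 digits) against 0.35 for the other 10, but only 3 of the 5 separated the groups and their values were low (7.16 to 84.6). An effect of the antagonist may be part of it and was not tested separately.

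The 2 linear relations among the 9 libraries may come from factors taken out on the log scale before rounding: the residual about them was at most 1.25 times the rounding error over 5 ranges of expression. The relations put weight above 0.1 on 7 and 8 libraries, but any mix of the 2 relations also holds. Those weights therefore cannot decide whether a library was deposited in 2 columns. Within the groups this is argued against by the closest pair of replicates, which differed by an SD of 0.249 in log2 value. That pair had 916 identical values among 13018 genes. No biological explanation was tested.

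Other splits of the same libraries were counted. For EAE against naive the real split gave 1853 genes, the only 1 of 10 splits with as many (highest other 13), and 17 lists, a number reached by 3 of 10 splits (highest other 18). For treated against EAE it gave 1 gene (1 of 10 splits, highest other 0) and 9 lists (8 of 10 splits, highest other 15), and for treated against naive 1932 genes (1 of 10 splits, highest other 0) and 19 lists (2 of 10 splits, highest other 19). With 10 splits the share cannot fall under 0.05. A split that mixes the groups keeps part of any difference between them, so its list calls are not a count without an effect. Among 100 splits of the 9 libraries into 3 groups, none but the real one gave as many as its 1728 genes (1 of 100, highest other 1653). Because the missing directions lay within the real groups, all these counts favour the real split, and the 100 splits do not exclude chance. The next of the 100 was the only other split drawn that kept the naive mice together, and splits that parted them gave at most 637 genes, so the count reflects naive mice against the other libraries and not the parting of treated from EAE mice.

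Chemosensory receptor genes had a median log2 fold change of -0.39, -0.35 and -0.75 over 709 tested genes in EAE against naive, treated against EAE and treated against naive mice, and 3, 0 and 30 of them fell by limma-trend. Genes with a mean under 20 (2190) had medians of -0.35, -0.16 and -0.54, against 0.06, 0.02 and 0.08 for genes from 100 (8705).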
